A study of Rattus norvegicus with 30 samples.

How the data were processed

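The deposited files are single-channel Agilent Feature Extraction tables for 30 rat arrays, 62976 spots each, of which 58717 were not controls. Per the file headers the processed signal is an intensity, background-subtracted and detrended within each array, with low signals replaced by a floor, and the files apply nothing between arrays. The headers name Feature Extraction 11.0.1.1 while the authors' notes name 10.3. The deposited series table holds log2 values. Within each array they followed the log2 of each probe's mean background-subtracted signal (smallest correlation over arrays 0.9993). The 119283 empty cells fell exactly where that mean was negative. Array medians lay between 7.23 and 7.24, but these checks do not show which scaling between arrays was applied.

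Spots of one probe were averaged after spots marked as outliers were left out, and 264 probe and array pairs kept all spots because none was left otherwise. The log2 of the processed signal was taken and each array's 75th percentile subtracted. The files lack gene names, so probes were named through their transcript accession: 18355 of 30367 probes (60.4%) matched a symbol and 12012 did not. The brightest probe stood for each gene. A gene was tested where it was well above background on at least 4 of 5 arrays of at least 1 group, which kept 18332 of 26785 genes and removed 8453. No probe was saturated.

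Genes were compared with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table and 2.0.0 of jsonlite), with 1 mean for each of 6 groups and moderated t-tests (median total degrees of freedom 26.3). Its p-values come from these models and not from exact or permutation tests. The p-values of each of 14 comparisons were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The comparisons were each perfused group against the non-perfused group of its diet, glucose against mannitol in each diet, the diets in each state, both effects averaged, and 3 interactions. Intervals are 95%.

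The samples, the groups, the main settings, the comparisons and 46 gene lists were chosen before the data were examined. Each list was tested with camera at a correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes move on balance one way and not whether they move more than other genes. List p-values were adjusted over the 46 lists of a comparison. The genes to name were also fixed by rule: the 8 largest rises and falls without overlap of the arrays, up to 4 called members of each list, genes given in advance (such as Txnip, Pdk4 and Angptl4 for glucose and diet, and Fos, Atf3 and Il6 for perfusion), and the 3 smallest p-values where nothing passed. Of the genes given in advance, Arrdc4 and Hspa1a were not among the tested genes.

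The alternatives were quantile normalization, the median of 13789 probes above background on all arrays, normexp background correction, the authors' deposited values, no filter, a filter on all 30 arrays, the mean of a gene's probes, and slide as a fixed or random block (consensus correlation 0.213). The others were replicate number as a block, only the compared groups, trend and robust options, array weights (0.46 to 2.329), leaving out the array alone on its slide, and leaving out each array in turn. Leaving out 4 arrays of noisy negative controls, alone or with the array alone on its slide, was chosen after the arrays were seen. The files hold no mean foreground signal, so normexp (offset 50) used the median foreground signal. Replicate numbers do not pair the samples: residuals of arrays with one number had a mean correlation of -0.038, against 0.01 for other numbers, while arrays of one slide had 0.211. All non-perfused and chow mannitol arrays lay in row 1 of their slides, all glucose arrays in row 2, and the sucrose mannitol arrays in row 1 (1) and row 2 (4). Row therefore cannot be separated from glucose in chow or from perfusion with glucose, and hardly from perfusion with mannitol in sucrose hearts, from diet with mannitol or from the mannitol interaction, while chow mannitol and chow non-perfused arrays share a row.

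The settings were tried on simulated data with known changes. In chow mannitol against chow non-perfused, 41.8% of genes were called at a true change of 0.5, 74.6% at 1 and 98.5% at 2. For the interactions 17.9% to 25.4% were called at 0.5 and 84.8% to 89.4% at 2, so small differences in response would mostly be missed. Each list test called 4 of 4 simulated lists shifted by 0.3 and 0 others. The simulated genes varied independently, so false calls from correlated genes were not tried.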

Results

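Transcript levels were measured in the left ventricle of male Sprague Dawley rats aged 16 to 18 weeks, with 30 one-colour Agilent arrays and 1 array per sample. The labels call the samples of a group biological replicates. Rats had eaten chow or, for 8 to 10 weeks, a high-sucrose diet, which the labels describe as a way to bring on insulin resistance. Hearts of each diet were either left without perfusion or, after cold arrest, reperfused outside the body as working hearts for 60 min. The buffer of the perfused hearts held 10 mmol/L hydroxybutyrate, 1 mmol/L acetoacetate and 2 mmol/L propionate. It also held glucose at 25 mmol/L or, as the osmotic control given in the labels, the sugar alcohol mannitol at the same concentration. Each of the 6 groups (chow or sucrose, and non-perfused, mannitol or glucose) had 5 arrays, and this number limits the precision.

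Between 48.8% and 75.4% of an array's probes were well above background, and the ranges of the 6 groups overlapped. They ran from 48.8% to 74.9% in the chow non-perfused group and from 51.0% to 73.5% in the sucrose non-perfused group. The mannitol groups ran from 59.9% to 75.4% (chow) and from 50.9% to 73.2% (sucrose), and the glucose groups from 52.3% to 73.2% (chow) and from 59.4% to 74.6% (sucrose). The standard deviation of the negative control spots passed 8 intensity units on 4 arrays: chow non-perfused replicate 2, sucrose non-perfused replicates 1 and 5, and sucrose mannitol replicate 5. Each of 4 slides carried all 6 groups, and sucrose mannitol replicate 1 was alone on its slide. The first principal component held 23.1% of the variance, and perfusion accounted for 98.2% of it. The next component held 13% of the variance, of which the slide accounted for 90.2%, and diet accounted for at most 8.18% of any of the first 5 components.

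Of 18332 genes tested, 11303 had a symbol. Changes are log2 differences of group means with the standard error (SE) of the limma fit, n = 5 arrays per group, and a gene is said to have risen or fallen where its adjusted p was under 0.05. Unless stated, the 5 values of one group did not overlap the 5 values of the other for a gene said to have risen or fallen in the accounts of perfusion. Where no array of one group was well above background, the fold is given as at least the fold to the lowest level called above background.

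The first comparison, chow hearts perfused with mannitol against chow non-perfused hearts, asks how transcript levels differ after reperfusion. The perfused hearts also went through cold arrest, work outside the body and a change from blood to buffer. These cannot be separated from reperfusion here. Genes of the immediate-early response and of inflammatory signalling rose the most, and genes of red blood cells fell the most. The nuclear receptor gene Nr4a3 rose 98.5-fold (6.62, SE 0.56) and was above background on 3 of 5 non-perfused arrays. The stress-induced transcription factor gene Atf3 rose 90.6-fold (6.50, SE 0.40), Fos, which encodes a subunit of the AP-1 transcription factor, rose 66.7-fold (6.06, SE 0.68), and the growth factor-induced regulator Egr1 rose 28.5-fold (4.83, SE 0.40). The neutrophil-attracting chemokine genes Cxcl2 and Cxcl1 rose 49.9-fold (5.64, SE 0.46) and 36.4-fold (5.18, SE 0.39). The beta-globin gene Hbb fell by 7.58 on the log2 scale (192-fold, SE 0.95).

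The nuclear receptor gene Nr4a1 rose 37.1-fold, and Zfp36, whose protein destabilises cytokine messages, rose 21.4-fold. Angptl4, which encodes an inhibitor of lipoprotein lipase, rose 14.7-fold (3.88, SE 0.51), and Pdk4, whose kinase inhibits pyruvate dehydrogenase, rose 3.11-fold (1.64, SE 0.23). Irs2, an adaptor of the insulin receptor, rose 10.6-fold and the extracellular protease gene Adamts1 rose 13.2-fold. The cytokine genes Ccl2 and Il6 rose 10.6-fold (3.41, SE 0.30) and 4.45-fold (2.15, SE 0.32), with Il6 above background on 2 of 5 non-perfused arrays. Nppb, the gene of a natriuretic peptide released by stretched heart muscle, rose 2.45-fold (1.29, SE 0.33) and Hmox1, which encodes a heme-degrading enzyme, 1.91-fold (0.93, SE 0.28). The tight junction gene Cldn5, expressed in endothelium, rose 3.77-fold (1.91, SE 0.13). Among the falls, the globin genes Hbb-bs, Hbe2 and Hbb-b1 fell 298-fold, 276-fold and 138-fold, and Hba-a1 fell 31.3-fold. Alas2, which encodes the erythroid enzyme that starts heme synthesis, fell 41.9-fold (-5.39, SE 0.36). Npy, which encodes the transmitter neuropeptide Y, fell 18.3-fold (-4.19, SE 0.41). S100a9, which encodes a calcium-binding protein of neutrophils, fell at least 14.6-fold. Gja5, a gap junction gene of the atria and conduction system, fell 2.59-fold. In total 1552 genes changed, 885 upward and 667 downward, and 244 rose and 80 fell at least 2-fold. The change had one sign within all 4 slides for 1510 of them (97.3%). These genes were called from the same arrays, which by itself raises this share, here and in the next 3 comparisons. The share over all tested genes was not computed.

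The next comparison asks the same of chow hearts perfused with glucose. Nr4a3 rose 153-fold (7.25, SE 0.56), Atf3 107-fold (6.74, SE 0.40) and Fos 100-fold (6.65, SE 0.68), and Egr1 rose 29.7-fold (4.89, SE 0.40). Egr2 and Egr4, relatives of Egr1, rose 33.0-fold and at least 17.7-fold. Hbb fell 267-fold (-8.06, SE 0.95), Hbb-bs 451-fold and Alas2 53.1-fold. Npy fell 18.7-fold (-4.23, SE 0.41), and 2 of the 5 glucose arrays were above background for it.

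Cxcl2 rose 64.7-fold and Ccl7, which encodes a monocyte-attracting chemokine, 16.2-fold (4.02, SE 0.31). Ccl2 and Il6 rose 14.4-fold and 6.95-fold. Angptl4 rose 21.8-fold (4.45, SE 0.51), Pdk4 3.48-fold (1.80, SE 0.23) and Plin2, which encodes a coat protein of lipid droplets, 1.61-fold (0.68, SE 0.10). Hk2, the gene of a hexokinase of muscle, rose 1.32-fold (0.40, SE 0.12, adjusted p = 0.0272), with overlap between the groups. Hmox1 rose 2.54-fold and Nppb 2.42-fold. Adamts4, a protease gene related to Adamts1, rose 5.71-fold from a level above background on 1 of 5 non-perfused arrays. Ucp2, which encodes a mitochondrial carrier, fell 1.81-fold (-0.86, SE 0.24), with overlap. S100a9 fell at least 9.98-fold and its partner gene S100a8 at least 3.95-fold, and the B cell receptor gene Cd79b fell at least 1.91-fold, with overlap. In total 1748 genes changed, 996 upward and 752 downward, with 288 rises and 99 falls of at least 2-fold. The sign was shared by all 4 slides for 1690 of them (96.7%).

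In sucrose-fed rats, hearts perfused with mannitol are compared with sucrose non-perfused hearts, which asks the same on the background of that diet. Fos rose 119-fold (6.89, SE 0.68), Cxcl2 86.1-fold (6.43, SE 0.46), Nr4a3 74.9-fold (6.23, SE 0.56), Atf3 62.9-fold (5.97, SE 0.40) and Egr1 37.3-fold (5.22, SE 0.40). Hbb fell 408-fold (-8.67, SE 0.95), and Npy fell 24.9-fold (-4.64, SE 0.41). Mrc1, which encodes a mannose receptor of resident macrophages, rose 2.92-fold (1.55, SE 0.25) from 3 of 5 non-perfused arrays above background.

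Gdf15, which encodes a stress-induced hormone, rose 23.0-fold (4.53, SE 0.35) and Angptl4 5.55-fold (2.47, SE 0.51), the latter with overlap between the groups. Pdk4 rose 2.22-fold (1.15, SE 0.23). Ccl2 rose 11.6-fold and Il6 5.60-fold. Bcl6, which encodes a transcriptional repressor, rose 2.21-fold, and Sesn3, which encodes a stress-responsive regulator of growth signalling, fell 1.58-fold (-0.66, SE 0.14). Hmox1 was 1.69-fold higher (0.76, SE 0.28, adjusted p = 0.0902) and Nppb 1.90-fold higher (0.93, SE 0.33, adjusted p = 0.0753), so neither passed the threshold. The Nppb values of the groups overlapped, with differences within slides from -0.329 to 2.303. Genes of small falls were Pln, which encodes the calcium pump inhibitor phospholamban (-0.33, SE 0.09), the respiratory chain gene Uqcr10 (-0.42, SE 0.08) and the ribosomal protein gene Rpl13 (-0.40, SE 0.09). The call of Rpl13 ended with quantile normalization. Clec1b, a platelet receptor gene, fell 5.22-fold with overlap and S100a9 6.83-fold, and these were above background on 1 and 2 of the mannitol arrays. In total 1999 genes changed, 1016 upward and 983 downward, with 279 rises and 60 falls of at least 2-fold. Rises made up 50.8% of them, against 88.9% of the 413 genes called in the authors' values. The sign was shared by all 4 slides for 1914 of them (95.7%). The count was 1252 without the 4 arrays of high control spread and 1022 without these and the array alone on its slide, and 1070 when the 2 groups were fitted alone.

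In sucrose hearts perfused with glucose, against the same non-perfused hearts, Cxcl2 rose 147-fold (7.20, SE 0.46) and Fos 142-fold (7.15, SE 0.68). Nr4a3 rose 82.4-fold (6.37, SE 0.56), Atf3 72.3-fold (6.18, SE 0.40) and Egr1 32.1-fold (5.00, SE 0.40). Hbb fell 493-fold (-8.95, SE 0.95), Hbb-bs 858-fold and Npy 23.6-fold (-4.56, SE 0.41). Cxcl1 rose 52.1-fold (5.70, SE 0.39), with glucose replicate 1 far above the other 4.

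Angptl4 rose 10.5-fold (3.39, SE 0.51), Pdk4 2.74-fold (1.45, SE 0.23) and Lipe, the gene of hormone-sensitive lipase, 1.80-fold (0.85, SE 0.17). Gfpt2, an enzyme gene that starts the hexosamine pathway, rose 2.54-fold (1.34, SE 0.24) with overlap, and Uap1, later in that pathway, rose 2.38-fold (1.25, SE 0.18). Ccl3 and Ccl2, chemokine genes of monocytes, rose 18.5-fold and 14.9-fold, and Il6 rose 5.84-fold. Hmox1 rose 2.15-fold (SE 0.28), and Nppb was 1.98-fold higher without passing the threshold (0.99, SE 0.33, adjusted p = 0.065). Dgat2, which encodes an enzyme of triglyceride synthesis, rose 2.00-fold (1.00, SE 0.25), and Slc16a3, a lactate transporter gene, 1.61-fold (0.68, SE 0.10). Rrm2, a ribonucleotide reductase gene of dividing cells, fell 1.63-fold with overlap (-0.71, SE 0.22). In total 1597 genes changed, 1016 upward and 581 downward, with 283 rises and 64 falls of at least 2-fold. The sign was shared by all 4 slides for 1514 of them (94.8%), and the count was 1046 when the 2 groups were fitted alone.

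Across the 4 perfusion comparisons, 595 genes rose in every one and 243 fell in every one, 471 and 198 of them with a symbol. The chow and sucrose changes with mannitol share no array, and they had a correlation of 0.716 across genes, which are not independent replicates. Of the genes called in both, 662 rose together (49.0 expected from the 2 counts) and 355 fell together (35.8 expected), and 0 went opposite ways. For glucose the correlation across genes was 0.797, with 775 shared rises (55.2 expected), 361 shared falls (23.8 expected) and 0 opposite calls. The mannitol and glucose changes of one diet use the same non-perfused arrays, which alone makes them alike. In chow their correlation was 0.89 against 0.499 in simulated data with no change, and with the non-perfused arrays divided between them the median over 20 divisions was 0.662. In sucrose the values were 0.879, 0.496 and 0.64, and 1 gene was called in opposite directions: Txnip, at -0.64 with mannitol and 0.64 with glucose (adjusted p = 0.0335 and 0.0393), with overlap in both. Over 4 slides the mannitol difference ran from -1.13 to -0.24 and the glucose difference from -0.38 to 1.08, so the latter changed sign. The glucose call ended without any one of sucrose non-perfused replicates 1, 2 and 5 and sucrose glucose replicates 1, 2, 4 and 5 (adjusted p up to 0.133), and the mannitol call for other arrays given with the carbohydrate-responsive genes.

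**Figure D1:**
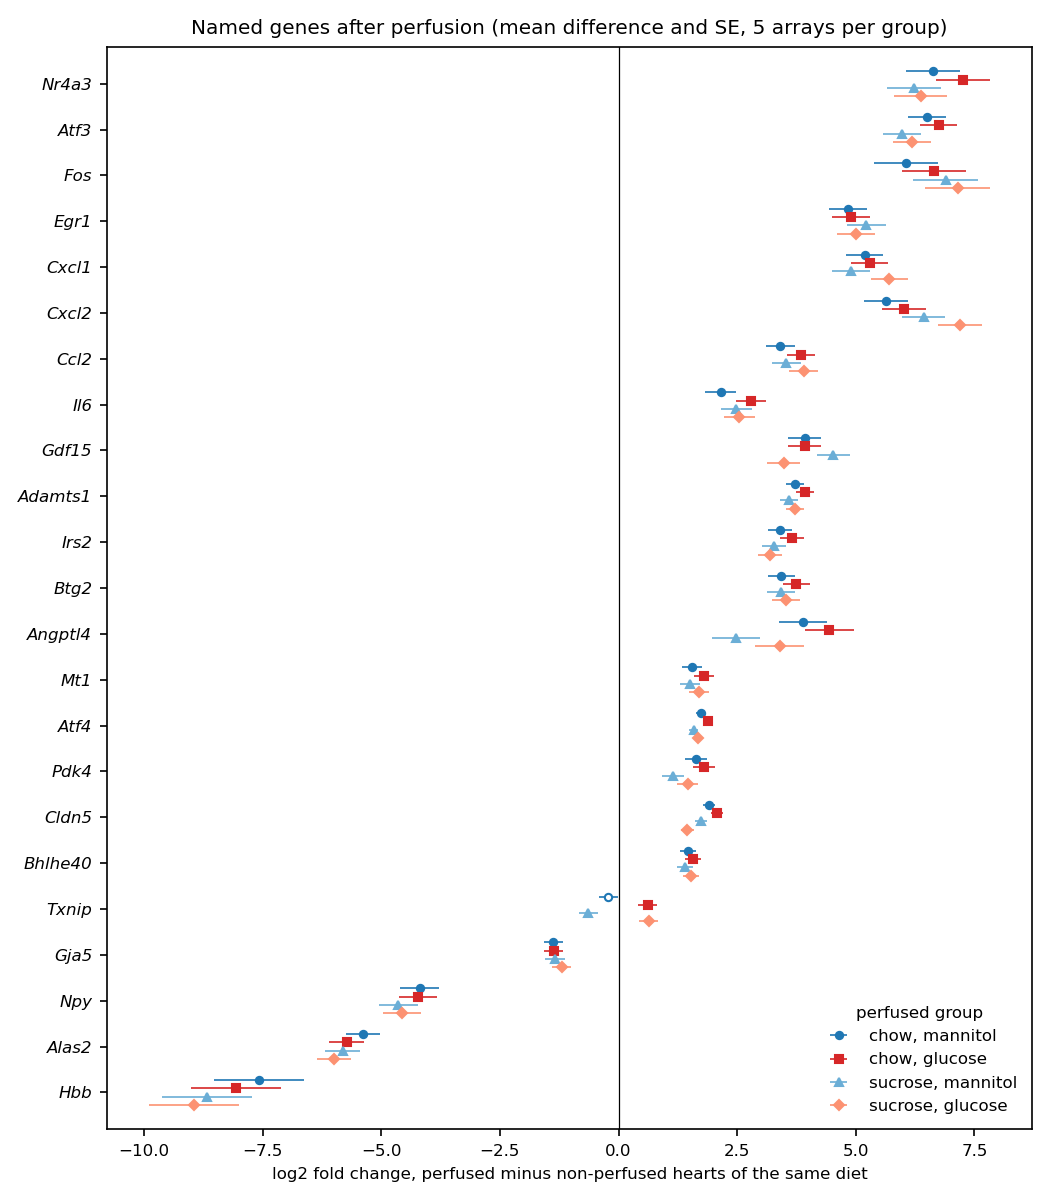
Log2 change (perfused minus non-perfused, bars ± SE, n = 5 arrays per group) of 23 named genes in the 4 perfusion comparisons, with filled points at an adjusted p under 0.05 and open points otherwise. Immediate-early and chemokine genes lie to the right (Nr4a3 from 6.23 to 7.25) and globin genes and Npy to the left (Hbb from -8.95 to -7.58).

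The gene groups fixed before the data were examined are described next, with values in the order chow mannitol, chow glucose, sucrose mannitol and sucrose glucose, each against non-perfused hearts. Each group was tested against all other genes with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The deposited values of the authors shifted the median change of all genes by -0.101 in the chow glucose comparison and 0.104 in the sucrose glucose comparison relative to the main scaling, and signs under that scaling are read against this shift.

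Of 40 measured immediate-early genes, which respond to a stimulus without new protein synthesis, 34, 36, 36 and 34 rose and none fell. Adjusted over the list alone, 34, 37, 37 and 34 rose. The median change ran from 2.34 to 2.59, and with an estimated correlation the adjusted p was 0.000105, 5.26e-05, 0.000116 and 0.000123. Among them the antiproliferative gene Btg2 rose 10.8-, 13.4-, 10.8- and 11.5-fold. Of 36 NF-kappaB targets and inflammatory mediators, 25, 25, 26 and 25 rose and none fell (27, 28, 26 and 26 adjusted over the list alone). Their median change ran from 1.34 to 1.58, and the adjusted p with an estimated correlation was 0.00129, 0.00107, 0.00237 and 0.00167. Of 24 genes of the integrated stress response, driven by the transcription factor ATF4, 7, 8, 9 and 7 rose and 2, 2, 2 and 1 fell. Adjusted over the list alone 9, 8, 9 and 8 rose and 2, 2, 3 and 2 fell. Their median change ran from 0.11 to 0.17 but was -0.05 for chow glucose in the authors' values, and the adjusted p with an estimated correlation was 0.00286, 0.00171, 0.00188 and 0.00175. Without the 4 arrays of high control spread the median was 0.05 with chow mannitol and 0.08 with sucrose mannitol. Ddit3, a transcription factor gene of that response, rose 4.35- to 4.59-fold (SE 0.12), Ppp1r15a, whose product directs the phosphatase that ends it, rose 4.77- to 5.90-fold (SE 0.14), and Atf4 itself rose 3.00- to 3.70-fold (SE 0.09).

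Clock genes, 16 measured, also moved as a group: 7, 5, 4 and 6 rose and none fell, and 8, 7, 6 and 9 rose and 1, 0, 0 and 1 fell adjusted over the list alone. The adjusted p with an estimated correlation was 0.00122, 0.00171, 0.004 and 0.00175. Without the 4 arrays of high control spread 7, 4, 4 and 3 clock genes rose and 0 fell. The clock repressor gene Bhlhe40 rose 2.63- to 2.97-fold (SE 0.16), and Ciart, another repressor of the clock, rose 7.56- to 12.1-fold (SE 0.77) with overlap and with 2 of 5 non-perfused arrays above background. Of 25 apoptosis and p53 genes, 8 rose in each comparison and 1, 2, 1 and 1 fell (8, 9, 9 and 8 up and 1, 2, 2 and 2 down adjusted over the list alone). Their adjusted p with an estimated correlation was 0.00318, 0.00245, 0.004 and 0.00175, and without the 4 arrays of high control spread the sucrose medians went from 0.23 to 0.07 and from 0.24 to 0.14. The survival gene Mcl1 rose 4.05- to 4.88-fold and the growth arrest gene Gadd45g 6.65- to 8.38-fold. Of 19 glucocorticoid-responsive genes, 9, 7, 8 and 8 rose and 2, 2, 1 and 1 fell (10, 9, 9 and 10 up and 2, 3, 1 and 1 down adjusted over the list alone), with an adjusted p of 0.0264, 0.00845, 0.0368 and 0.0327 under an estimated correlation. Errfi1, a feedback inhibitor of the epidermal growth factor receptor, rose 3.89- to 5.40-fold, and Ddit4, an inhibitor of mTOR signalling, fell 1.36- to 1.52-fold, with overlap in both sucrose comparisons.

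Some groups kept their call in part of the comparisons once the correlation was estimated. Of 26 FOXO targets and insulin signalling genes, 7, 7, 8 and 6 rose and 1, 1, 2 and 1 fell (8, 7, 8 and 10 up and 1, 2, 2 and 1 down adjusted over the list alone). All 4 were called by camera, and with an estimated correlation the adjusted p was 0.0123, 0.00833, 0.0849 and 0.0327. Their median in the sucrose mannitol comparison was 0.04 and turned to -0.01 with normexp background correction. Of 30 NRF2 targets, which protect against oxidants, 7, 11, 8 and 9 rose and 3 fell in the sucrose mannitol comparison alone (10, 11, 9 and 9 up and 0, 1, 3 and 1 down adjusted over the list alone). Without the 4 arrays of high control spread 6, 9, 6 and 6 rose and 0 fell, and the sucrose mannitol median went from 0.07 to 0.02. All 4 were called by camera, and the adjusted p with an estimated correlation was 0.0662, 0.0102, 0.114 and 0.0556. Osgin1, an NRF2 target, rose 5.14- to 7.09-fold, and the metallothionein gene Mt1 rose 2.86- to 3.5-fold. Of 28 matrix and remodelling genes, 8, 12, 10 and 11 rose and 1 fell in the last comparison (10, 12, 13 and 11 up and 1, 0, 1 and 3 down adjusted over the list alone). All 4 were called by camera, the adjusted p with an estimated correlation was 0.0725, 0.0212, 0.0138 and 0.0425, and the chow glucose median of 0.08 turned to -0.02 in the authors' values. Thbs1, which encodes the adhesive protein thrombospondin, rose at least 3.75-, 4.35-, 3.12- and 2.70-fold, with overlap in the last.

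Of 29 heat shock and chaperone genes, 8, 6, 7 and 7 rose and 0, 0, 1 and 1 fell (8, 8, 9 and 7 up and 0, 1, 2 and 1 down adjusted over the list alone). The chow comparisons were called (adjusted p with an estimated correlation 0.0135 and 0.00245) and the sucrose comparisons were not (camera 0.0825 and 0.0618). In sucrose the medians were -0.004 and -0.005 while the means were 0.138 and 0.14, and these medians turned positive with quantile normalization. The co-chaperone gene Dnajb4 rose 1.96- to 2.60-fold (SE 0.13). Of 20 genes of the unfolded protein response of the endoplasmic reticulum, none rose and 3, 2, 4 and 4 fell (0, 0, 1 and 0 up and 6, 2, 6 and 5 down adjusted over the list alone). Camera called 3 of the 4 as lower, and the adjusted p with an estimated correlation was 0.331, 0.638, 0.385 and 0.286. Without the 4 arrays of high control spread 4, 3, 2 and 2 of these genes fell. Sec61b, a subunit of the translocation channel, fell 1.29- to 1.34-fold, with overlap for chow glucose. Of 23 carbohydrate-responsive genes, targets of the glucose-sensing factors MondoA and ChREBP, 4, 4, 4 and 6 rose and 1 fell with sucrose mannitol (4, 5, 5 and 7 up and 1 down there adjusted over the list alone). Both glucose comparisons were called by camera, and these calls were lost with an adjusted p of 0.0547 and 0.11 under an estimated correlation. Their chow glucose median of 0.07 was -0.002 in the authors' values, and for chow mannitol the median (-0.007) and the mean (0.088) differed in sign. Rgs16, a regulator of G protein signalling, rose 2.36- to 3.78-fold (SE 0.20), and Klf10, a zinc finger factor gene, 2.01- to 3.04-fold (SE 0.19). The gene that fell was Txnip (-0.64, SE 0.20, adjusted p = 0.0335, with overlap), whose call ended without any one of sucrose non-perfused replicates 1, 3 and 4 and sucrose mannitol replicates 2, 4 and 5 (adjusted p up to 0.104).

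Of 23 cell cycle genes, 2 rose in each comparison and 3, 5, 1 and 4 fell (2 up each and 7, 10, 2 and 7 down adjusted over the list alone). Camera called both chow comparisons as lower, with an adjusted p of 0.271 and 0.288 under an estimated correlation. Without the 4 arrays of high control spread 5, 5, 1 and 1 cell cycle genes fell. Pcna, the clamp of DNA polymerase that also serves DNA repair, rose 1.63- to 1.92-fold in all 4, while Mki67, a marker of dividing cells, fell 1.54-fold with chow glucose, with overlap, and 1.52-fold with sucrose glucose. Of 77 ribosomal protein genes, 1, 0, 25 and 2 fell and none rose (0, 0, 34 and 2 adjusted over the list alone). Their median was -0.20 with sucrose mannitol, where the adjusted p was 0.0186 with an estimated correlation, but with quantile normalization this median was -0.05 and 0 genes fell, and without the 4 arrays of high control spread 10 genes fell. The camera calls of both glucose comparisons gave an adjusted p of 0.528 and 0.101 with an estimated correlation, and the sucrose glucose median of -0.12 turned to 0.02 in the authors' values. Of 74 genes of oxidative phosphorylation, 1, 1, 20 and 2 fell and 1 rose in each (adjusted over the list alone 33 fell with sucrose mannitol and none in the others). That rise was Uqcrq, a subunit of complex III (2.56- to 3.19-fold). Their median was -0.19 with sucrose mannitol, where 8 fell without those 4 arrays, and -0.12 with sucrose glucose. These camera calls gave an adjusted p of 0.116 and 0.286 with an estimated correlation, and the medians turned to 0.03 and 0.04 in the authors' values. Of 67 mitochondrial ribosomal genes, 3, 7, 10 and 7 fell (2, 7, 13 and 7 adjusted over the list alone), and 1, 3, 5 and 2 without those 4 arrays, all 4 camera calls being lost at an adjusted p of 0.331, 0.422, 0.145 and 0.195 with an estimated correlation. Of 40 proteasome genes, 1, 1, 0 and 0 rose and 1 fell in each (1, 0, 0 and 0 up and 1, 0, 1 and 0 down adjusted over the list alone), and the camera call with sucrose mannitol gave an adjusted p of 0.385 with an estimated correlation. Its median of -0.10 turned to 0.01 in the authors' values.

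Markers of cell types other than muscle moved as follows. Of 11 erythroid genes, 6 fell in every comparison, also adjusted over the list alone, where 1 rose with sucrose mannitol, and the adjusted p with an estimated correlation was 0.0133, 0.00845, 0.0291 and 0.0151. Of 6 platelet genes, 3, 3, 1 and 2 fell (3, 3, 2 and 2 adjusted over the list alone). Camera called all but sucrose mannitol, and the adjusted p with an estimated correlation was 0.0175, 0.0274, 0.252 and 0.0836. Of 8 neutrophil genes, 2 fell in each (S100a8, with overlap in sucrose, and S100a9), also over the list alone, and camera made no call (0.0834, 0.193, 0.361 and 0.093). Within slides S100a8 changed sign in sucrose, from -3.824 to 1.569 with mannitol and from -4.744 to 0.788 with glucose. Of 15 lymphocyte genes, 1, 5, 5 and 5 rose and 2, 2, 1 and 1 fell (4, 8, 7 and 7 up and 2, 2, 1 and 2 down adjusted over the list alone). The last 3 comparisons were called by camera, with an adjusted p of 0.237, 0.116 and 0.215 under an estimated correlation, and in the first the median (0.34) and the mean (-0.003) differed in sign. Without the 4 arrays of high control spread, 2 lymphocyte genes rose in each sucrose comparison and the medians there went from 0.49 to 0.20 and from 0.42 to 0.08. Gzmb, a protease gene of cytotoxic lymphocytes, rose 2.14- to 3.33-fold (SE 0.29), and Cd79b fell at least 1.85- to 2.96-fold, with overlap in 2 of the 4.

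Of 18 macrophage and monocyte genes, 0, 1, 6 and 5 rose (0, 0, 14 and 7 adjusted over the list alone). Camera called the last 3 comparisons, and the adjusted p with an estimated correlation was 0.55, 0.0849 and 0.11. Without the 4 arrays of high control spread, 3 macrophage genes rose in each sucrose comparison, at medians of 0.41 and 0.43. Lyve1, a hyaluronan receptor gene, rose 1.67-fold with sucrose mannitol and 1.5-fold with sucrose glucose, both with overlap. Of 12 endothelial genes, 2, 2, 3 and 2 rose (2, 3, 3 and 4 adjusted over the list alone), all called by camera, with an adjusted p of 0.186, 0.0241, 0.152 and 0.208 under an estimated correlation, and the sucrose glucose median of 0.04 was -0.01 without those 4 arrays. Cldn5 rose 2.73- to 4.21-fold and the receptor gene Flt1 1.29- to 1.79-fold. Of 14 fibroblast genes, 1, 2, 2 and 2 rose (the same numbers adjusted over the list alone), and the camera calls with sucrose were lost at an adjusted p of 0.329 and 0.404 with an estimated correlation. In chow glucose their median (0.01) and mean (-0.003) differed in sign. Of 13 smooth muscle and pericyte genes, 1 rose in each (1, 1, 2 and 2 adjusted over the list alone), and the call with sucrose glucose gave an adjusted p of 0.342 with an estimated correlation. Of 16 cardiomyocyte genes, none rose and 1 fell, Pln with sucrose mannitol, also adjusted over the list alone. That list was called as lower there by camera, with an adjusted p of 0.385 under an estimated correlation, and its median of -0.24 turned to 0.04 with quantile normalization and 0.04 in the authors' values.

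The other 21 lists had no camera call in any of the 4 comparisons (adjusted p between 0.0834 and 0.989), and the signs of many of their medians differed from the mean or turned with the scaling. The medians lay within 0.25 of 0, apart from mesothelial markers (-0.52, -0.63 and -0.43 in all but sucrose mannitol), atrial markers in chow (-0.41 and -0.55) and lung markers with sucrose glucose (0.37). Neutrophil genes are given above. In numbers that rose, then fell, interferon-stimulated genes (28 measured) gave 2, 3, 3 and 2 rises, glycolysis (28) 1, 2, 1 and 1 rises, and the pentose phosphate and polyol pathway (12) 1 rise with sucrose mannitol and 2, 1, 2 and 0 falls. Without the 4 arrays of high control spread, 0 interferon-stimulated genes rose and 2 fell with chow mannitol (median -0.184). The hexosamine pathway (13) gave 1, 1, 2 and 4 rises and 1 fall with sucrose mannitol, and glycogen metabolism (19) gave 0 of each. Fatty acid oxidation (45) gave 5, 4, 3 and 3 rises and 1, 1, 2 and 0 falls, ketone and propionate metabolism (19) 0, 0, 1 and 1 rises, and branched-chain amino acid breakdown (15) 0 of each. The tricarboxylic acid cycle (28) gave 2, 2, 1 and 2 rises and 1 fall with sucrose mannitol, and cholesterol synthesis (21) 3, 3, 2 and 3 rises and 1 fall in each. Insig1, which holds the sterol sensor in the endoplasmic reticulum, rose 2.19- to 2.51-fold (SE 0.11). Hypoxia targets (25) gave 3, 3, 1 and 3 rises and 1 fall in each, and Vegfa, which drives vessel growth, rose 1.41- to 1.91-fold, with overlap for sucrose mannitol. Hypertrophy genes (18) gave 2, 2, 1 and 1 rises and 0, 1, 1 and 0 falls, ion channels (28) 1, 1, 0 and 1 rises and 1 fall with sucrose mannitol, and autophagy (26) 1, 3, 2 and 2 rises and 1, 1, 2 and 1 falls. Adipocyte markers (7) gave 1, 1, 1 and 2 rises, atrial markers (8) 1, 1, 1 and 2 rises and 1, 1, 2 and 1 falls, and Schwann cell and neuron markers (14) 0, 1, 0 and 1 rises and 2, 2, 1 and 1 falls. The atrial light chain gene Myl4 fell with sucrose mannitol (-0.20, SE 0.06, with overlap), but its sign turned with quantile normalization (0.02) and in the authors' values (0.10). Mesothelial markers (8) gave 1 rise in each, lung markers (5) 1 fall in each sucrose comparison, and skeletal muscle markers (8) 0 of each. For these 21 lists the numbers adjusted over the list alone differed from those given by at most 2 genes in either direction. Fry, unlike camera, called neutrophil genes as lower in all 4 (adjusted p = 0.00149, 0.00696, 0.0328 and 0.0044), and hypoxia and adipocyte genes as higher in both glucose comparisons. It also called hexosamine genes as higher with sucrose glucose, pentose phosphate and skeletal muscle genes as lower with sucrose mannitol, and Schwann cell and neuron genes as lower with chow mannitol.

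**Figure D2:**
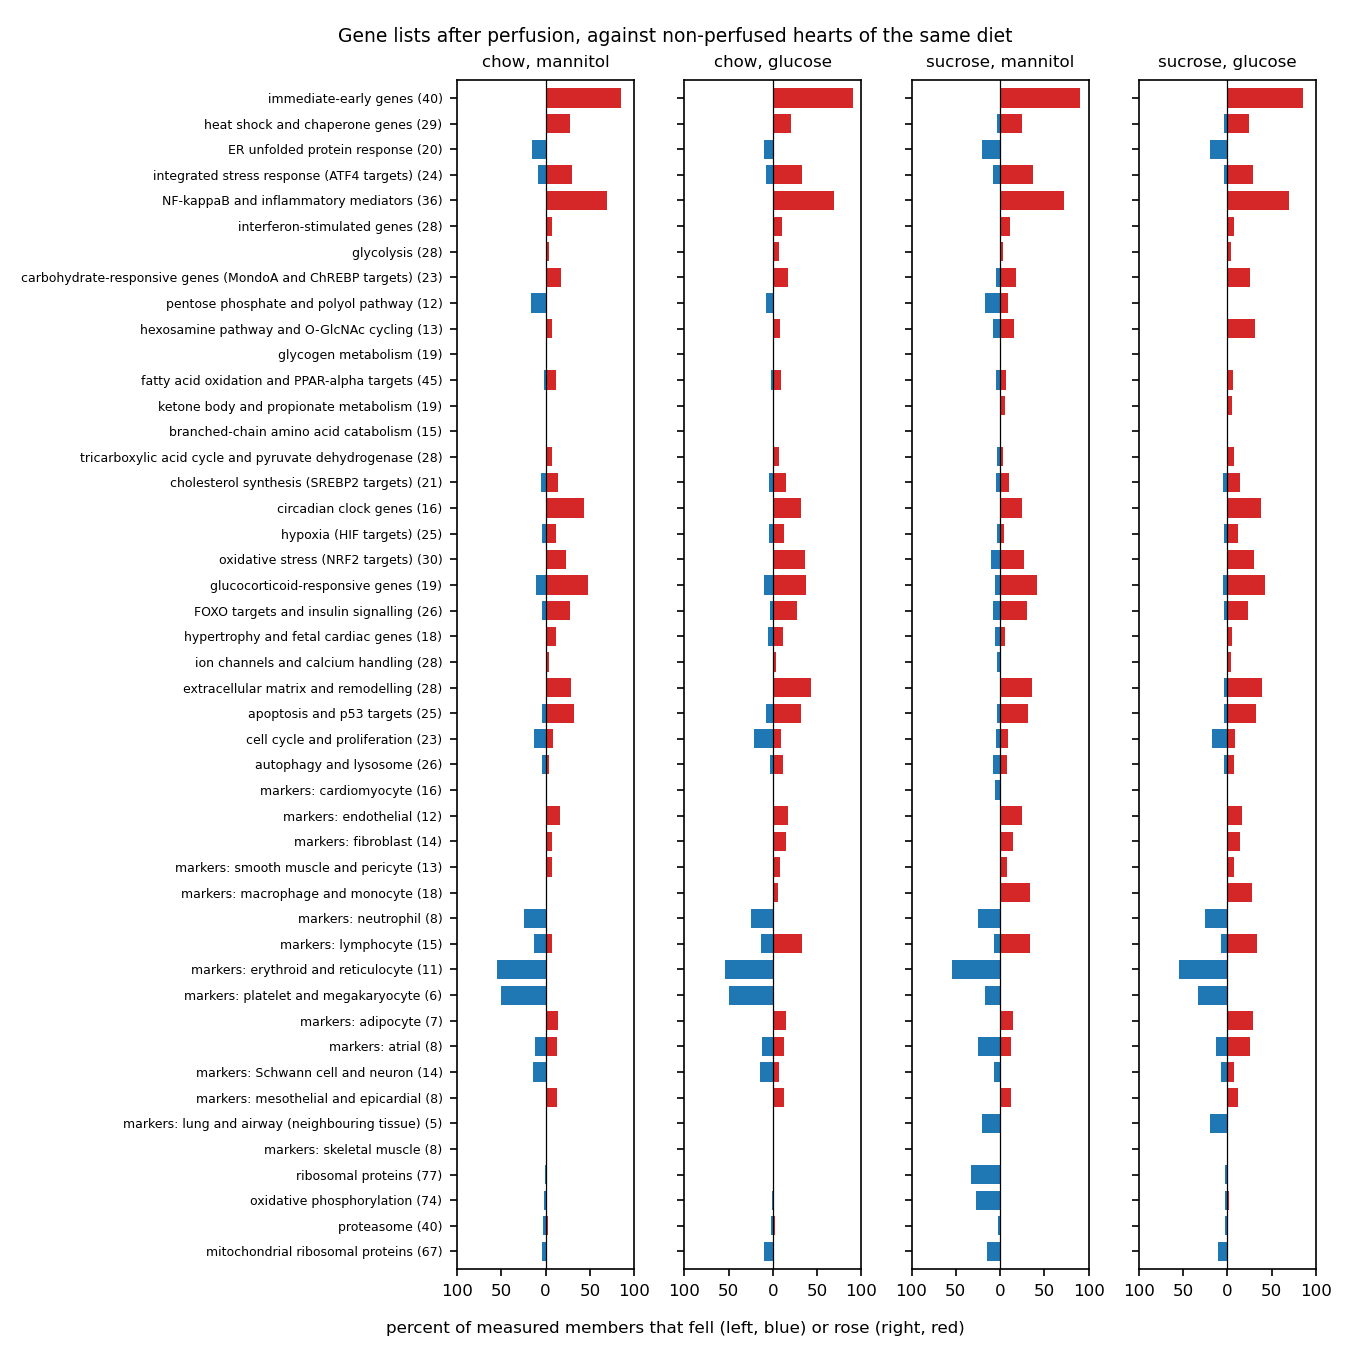
Percent of the measured members of each of 46 lists that rose or fell at an adjusted p under 0.05, in each of the 4 perfusion comparisons (colour, n = 5 arrays per group). Immediate-early genes (34, 36, 36 and 34 of 40 rose) and erythroid genes (6 of 11 fell in each) stand out; the 25 ribosomal protein genes that fell with sucrose mannitol number 0 with quantile normalization.

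Glucose was then compared with mannitol, its osmotic control, in chow hearts. This asks what 25 mmol/L glucose in place of mannitol does during reperfusion. No glucose concentration is given for the mannitol hearts, so a high glucose level is not compared with a lower stated one. Txnip, whose product restrains glucose uptake and binds thioredoxin and whose transcription follows glucose through MondoA, was higher with glucose but did not pass the threshold. It was 1.78-fold higher with glucose (0.83, SE 0.20, 95% interval 0.43 to 1.24), at an unadjusted p of 0.000232 and an adjusted p of 1, and the difference was between 0.42 and 0.95 in each of the 4 slides. All chow mannitol arrays lay in one row of their slides and all chow glucose arrays in the other, so glucose cannot be separated from the row here. S1pr1, a receptor gene for a lipid mediator in endothelium, was 1.35-fold higher (0.43, SE 0.09, unadjusted p = 7.15e-05, adjusted p = 1). Angptl4 was 1.48-fold higher (0.56, SE 0.51), and Pdk4 was at 0.16 (SE 0.23), the uncoupling protein gene Ucp3 at 0.25 (SE 0.44) and Hk2 at 0.10 (SE 0.12), none past the threshold. The glucose transporter genes Slc2a1 (-0.06, SE 0.17) and Slc2a4 (-0.04, SE 0.08) and the ketone enzyme gene Bdh1 (-0.07, SE 0.20) did not differ detectably. limma called 0 genes, with 711 at an unadjusted p under 0.05 where chance gives 917. Camera called 11 lists as higher and fry, which asks whether a list's genes move one way, called 0. The camera calls included immediate-early genes (median 0.19, adjusted p = 0.445 with an estimated correlation), NF-kappaB targets (0.15, 0.546 likewise) and carbohydrate-responsive genes (0.03, adjusted p = 0.299 with an estimated correlation), in which Txnip passed adjusted over the list alone. The median of the last list was -0.06 in the authors' values. The other 8 were interferon, NRF2, glucocorticoid, matrix, autophagy, endothelial, lymphocyte and proteasome genes, with an adjusted p between 0.299 and 0.629 with an estimated correlation.

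In sucrose hearts, Txnip rose with glucose, 2.41-fold over mannitol (1.27, SE 0.20, 95% interval 0.87 to 1.67, adjusted p = 0.0118). Its level went from 2.82 ± 0.26 (SD, n = 5) with mannitol to 4.09 ± 0.36 with glucose on the log2 scale, against 3.46 ± 0.36 without perfusion. The 5 values of each group did not overlap, and the rise was between 0.75 and 1.74 in each of 4 slides. Angptl4 was 1.89-fold higher (0.92, SE 0.51, adjusted p = 0.996), Pdk4 1.24-fold (0.31, SE 0.23) and Hk2 1.15-fold (0.20, SE 0.12), without passing the threshold. Ucp3 (-0.36, SE 0.44), Slc2a1 (0.08, SE 0.17), Slc2a4 (0.09, SE 0.08) and Bdh1 (0.14, SE 0.20) did not pass either. Txnip was the 1 gene called, with 872 genes at an unadjusted p under 0.05. Its call ended when any one of sucrose mannitol replicate 5 (adjusted p = 0.0642) or sucrose glucose replicates 1 (0.0668), 2 (0.0615), 4 (0.0629) and 5 (0.0875) was left out, at changes of 1.19 to 1.25, and in the authors' values (1.37, adjusted p = 0.155). It also ended with replicate number as a block (adjusted p = 0.0817), without the 4 arrays of high control spread (1.24, 0.0545), without these and the array alone on its slide (1.34, 0.0714), and in a fit of only the compared groups, where 0 genes were called. Zfp354c, a zinc finger gene, was 2.32-fold lower (-1.21, SE 0.24, adjusted p = 0.274), and it was called with slide as a block (-1.38, adjusted p = 0.0243), with array weights and without the array alone on its slide. Camera called ribosomal proteins (median 0.09) and oxidative phosphorylation (0.08, and -0.002 with quantile normalization) as higher, each with an adjusted p of 0.815 under an estimated correlation, and fry called 0 lists.

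Over both diets together, Txnip rose 2.07-fold with glucose (1.05, SE 0.14, 95% interval 0.77 to 1.34, adjusted p = 0.000755). It was again the 1 gene called, with 627 genes at an unadjusted p under 0.05, and it stayed called with any 1 of the 20 arrays left out (adjusted p at most 0.00297). With slide as a block its rise was 1.08 (SE 0.15, adjusted p = 0.00557). Angptl4 was 1.67-fold higher (0.74, SE 0.36, unadjusted p = 0.05), without passing, and Hk2 1.11-fold (0.15, SE 0.08). Of the 23 carbohydrate-responsive genes 1 rose (2 adjusted over the list alone), and the list's camera call gave an adjusted p of 0.477 with an estimated correlation. NF-kappaB targets were called as higher by camera (median 0.16), at an adjusted p of 0.499 with an estimated correlation, and so were immediate-early genes (0.06, adjusted p = 0.727 with an estimated correlation) and NRF2 targets (0.07, adjusted p = 0.477 with an estimated correlation). The glucose differences of the 2 diets had a correlation of -0.009 across genes.

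**Figure D3:**
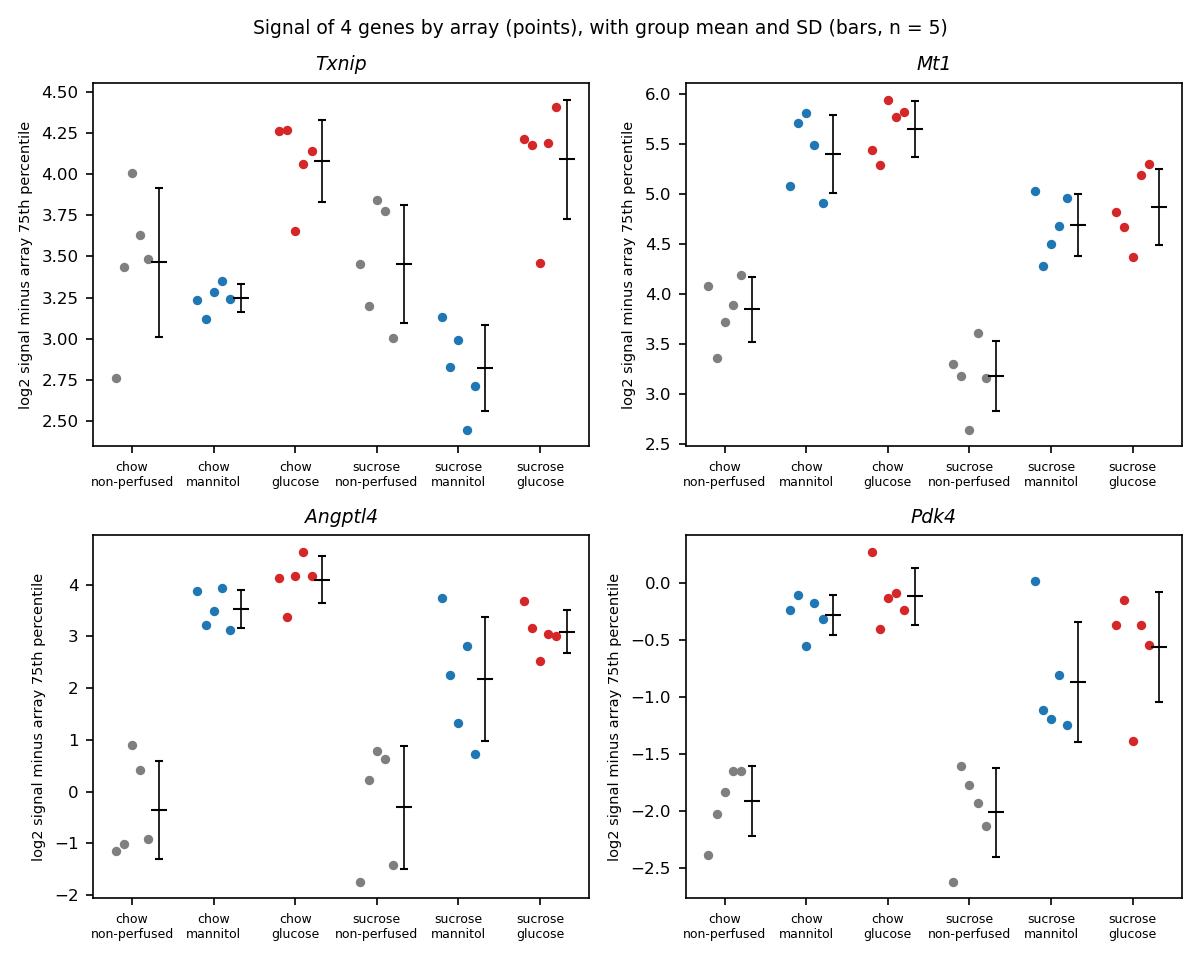
Log2 level relative to the array's 75th percentile of Txnip, Mt1, Angptl4 and Pdk4 in each array (points) of the 6 groups, with the mean ± SD (n = 5). Txnip is higher with glucose than with mannitol in both diets (means 4.08 against 3.25 in chow and 4.09 against 2.82 in sucrose), and Mt1 is lower on sucrose in all 3 states (3.18 against 3.85 without perfusion).

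Diet was compared first in hearts without perfusion, which asks what the high-sucrose diet does to the heart in the animal. limma called 0 genes, with 616 at an unadjusted p under 0.05, and no gene with a symbol came near the threshold. Tubg1, which encodes the gamma-tubulin of microtubule organising centres, was 1.23-fold higher on sucrose (0.30, SE 0.07, unadjusted p = 0.00031, adjusted p = 1). Txnip (-0.01, SE 0.20), Pdk4 (-0.10, SE 0.23) and Angptl4 (0.05, SE 0.51) did not differ detectably, nor did Ucp3 (-0.14, SE 0.44), Hk2 (0.13, SE 0.12), Slc2a1 (0.17, SE 0.17), Slc2a4 (0.02, SE 0.08) or Bdh1 (-0.03, SE 0.20). Hk2 was at -0.06 in the authors' values. Camera called 4 lists: fatty acid oxidation and PPAR-alpha targets (median -0.07) and macrophage markers (-0.13) as lower, and proteasome (0.03) and cardiomyocyte markers (0.08) as higher. Each gave an adjusted p of 0.899 with an estimated correlation, and the last 2 medians turned to -0.05 and -0.03 in the authors' values. Fry called 0 lists.

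In hearts perfused with mannitol, the diets differed in 1 gene, a probe without a symbol (A_64_P072347) that fell by 0.44 on sucrose (SE 0.07, adjusted p = 0.0176). It lost its call without any one of chow mannitol replicates 1, 2 and 4 and sucrose mannitol replicates 3, 4 and 5, when no gene was called. Angptl4 was 2.57-fold lower on sucrose (-1.36, SE 0.51, adjusted p = 0.498), Pdk4 1.5-fold lower (-0.59, SE 0.23, adjusted p = 0.525) and Txnip 1.34-fold lower (-0.43, SE 0.20, adjusted p = 0.611), none past the threshold. An unadjusted p under 0.05 was found for 1435 genes, where chance gives 917, but 4 of 5 sucrose mannitol arrays lay in the other row of their slides than all chow mannitol arrays, so diet can hardly be separated from the row here. Camera called 11 lists, 4 as lower and 7 as higher on sucrose. Fry called 3 of these, each as lower: fatty acid oxidation (median -0.14, adjusted p = 0.278 with an estimated correlation), ribosomal proteins (-0.12, 0.278 likewise) and oxidative phosphorylation (-0.12, 0.278 likewise). Adjusted over the list alone, 1 fatty acid oxidation gene rose and 3 fell, and 5 of oxidative phosphorylation fell. The last median was 0.001 with quantile normalization. Cardiomyocyte markers were the other list called as lower (-0.21, adjusted p = 0.394 with an estimated correlation, and 0.01 with quantile normalization). Interferon, matrix, cell cycle, fibroblast, macrophage, lymphocyte and mesothelial genes were called as higher, with an adjusted p between 0.278 and 0.622 with an estimated correlation.

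In hearts perfused with glucose limma called 0 genes between the diets, with 783 at an unadjusted p under 0.05. Hdac8, which encodes a histone deacetylase, was 1.64-fold higher on sucrose (0.71, SE 0.16, adjusted p = 0.565), and 3 of 5 chow arrays were above background for it. Angptl4 was 2.01-fold lower (-1.01, SE 0.51), Pdk4 1.36-fold lower (-0.45, SE 0.23) and Txnip did not differ detectably (0.01, SE 0.20), each at an adjusted p of 1. Camera called 9 lists and fry 0. Fatty acid oxidation (median -0.11), glucocorticoid-responsive (-0.26) and endothelial genes (-0.12) were lower and atrial markers (0.29) higher, each with an adjusted p of 0.0903 under an estimated correlation, and immediate-early genes were lower (-0.27, adjusted p = 0.298 with an estimated correlation). The other 4 calls, of heat shock, cholesterol, NRF2 and cell cycle genes, had an adjusted p between 0.0903 and 0.543 with an estimated correlation.

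Taken over the 3 states, 1 gene differed between the diets. The metallothionein gene Mt1, whose protein binds zinc and copper and is induced by metals, oxidants and glucocorticoids, fell 1.65-fold on sucrose (-0.72, SE 0.12, 95% interval -0.97 to -0.47, adjusted p = 0.0472). Its mean level on sucrose against chow was 3.18 ± 0.35 against 3.85 ± 0.33 (SD, n = 5) without perfusion, 4.69 ± 0.32 against 5.40 ± 0.39 with mannitol and 4.87 ± 0.38 against 5.66 ± 0.28 with glucose. Pdk4 was 1.30-fold lower (-0.38, SE 0.13, unadjusted p = 0.00832, adjusted p = 0.659) and Angptl4 1.71-fold lower (-0.77, SE 0.29, adjusted p = 0.725), without passing. Of 45 genes of fatty acid oxidation and PPAR-alpha targets, which burn the heart's main fuel, none passed over all genes, while 13 fell and 1 rose adjusted over the list alone. Their median was -0.12, fry called the list (adjusted p = 0.0082), and the camera call was lost at an adjusted p of 0.0574 with an estimated correlation. Glucocorticoid-responsive genes (median -0.10, 2 of 19 fell adjusted over the list alone) gave an adjusted p of 0.366 with an estimated correlation, and cell cycle genes (median 0.08) 0.355. The other 8 lists that camera called had an adjusted p between 0.588 and 0.626 with an estimated correlation. In total 1172 genes had an unadjusted p under 0.05. Mt1 lost its call in 21 of the 30 fits that left out 1 array (adjusted p at most 0.125), keeping it without chow glucose replicate 2, chow mannitol replicates 1 and 5, chow non-perfused replicate 2, sucrose glucose replicates 4 and 5, sucrose mannitol replicates 1 and 5 and sucrose non-perfused replicate 4. With slide as a block it fell by 0.73 (adjusted p = 0.0379). The call ended in the authors' values (adjusted p = 0.19), with quantile normalization (0.0564), with replicate number as a block, without the 4 arrays of high control spread (0.0849), without these and the array alone on its slide, and without the filter, where 0 genes were called.

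The last comparisons ask whether diet altered the response to perfusion or to glucose. limma called 0 genes for perfusion with mannitol (1134 at an unadjusted p under 0.05), for perfusion with glucose (482) and for glucose against mannitol (899). For mannitol, Ctf1, which encodes the cytokine cardiotrophin, had a response 1.57-fold lower on sucrose (-0.65, SE 0.13, unadjusted p = 3.81e-05, adjusted p = 0.349), and Angptl4 2.66-fold lower (-1.41, SE 0.72, adjusted p = 0.811). For glucose, Tapbp, a chaperone gene of antigen presentation, had a response 1.40-fold lower (-0.48, SE 0.12, unadjusted p = 0.000534, adjusted p = 1). The rise of Txnip with glucose over mannitol was not shown to differ between the diets (0.44, SE 0.28, 95% interval -0.13 to 1.01, adjusted p = 1). Camera called 8, 9 and 7 lists and fry 0. With mannitol, cardiomyocyte (median -0.26), ribosomal (-0.13) and oxidative phosphorylation genes (-0.16) had lower responses on sucrose and macrophage markers (0.28) a higher one, each with an adjusted p of 0.318 under an estimated correlation. With quantile normalization the medians of ribosomal and oxidative phosphorylation genes were 0.001 and 0.02. The cardiomyocyte median of sucrose mannitol against sucrose non-perfused hearts also turned in sign there.

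**Figure D4:**
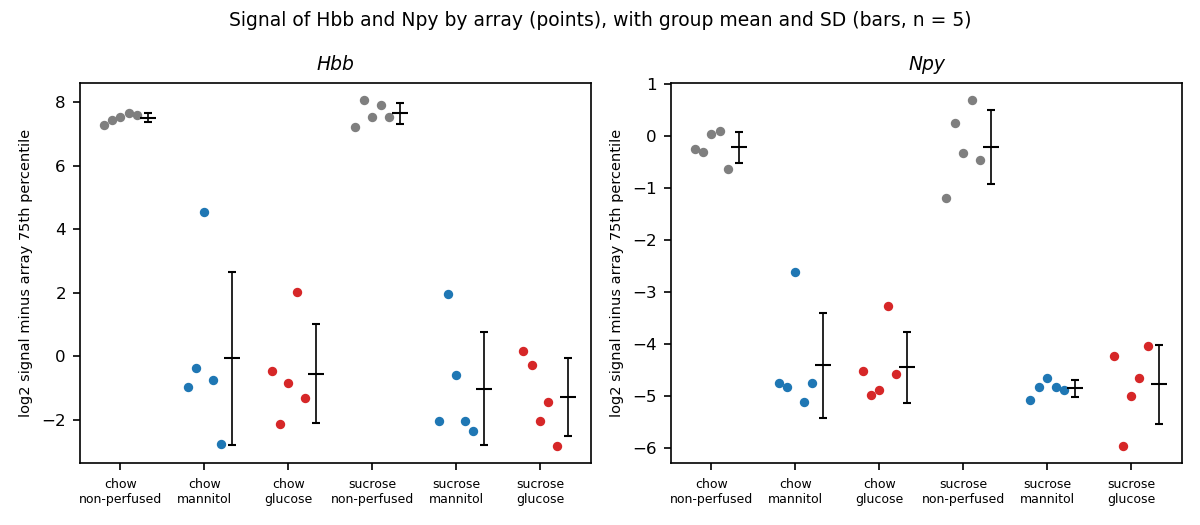
Log2 level relative to the array's 75th percentile of Hbb and Npy in each array (points) of the 6 groups, with the mean ± SD (n = 5). Hbb falls from means of 7.52 and 7.66 without perfusion to between -1.29 and -0.06 with perfusion, and Npy from -0.22 and -0.21 to between -4.85 and -4.41.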

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

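Which results to weigh was settled after the results were seen. What the relations to other blood cell genes and of Npy to erythroid genes in non-perfused hearts, the array quality test, the slide block and the splits should show was written down before those tests were run, while nothing was written down for Npy and Clec1b. The tests of perfused hearts, of erythroid genes within slides, of Th and Dbh, of cell share and of brightness were chosen after.

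Genes of red blood cells fell the most in all 4 perfusion comparisons (Hbb 192-fold to 493-fold). Blood left in non-perfused hearts and washed out by the buffer may account for this, but the levels of 6 erythroid genes and of 4 genes of neutrophils, B cells and platelets in the 10 non-perfused hearts could not settle it (Pearson r = 0.371, permutation p = 0.445, adjusted p = 0.509, Spearman rho = 0.236 with permutation p = 0.541, r without the 2 farthest arrays 0.392, and r = 0.723 with slide as a block, for which no p was computed). The 4 genes were S100a8, S100a9, Cd79b and Clec1b, members of their lists that fell with perfusion, so they do not stand for the whole lists. Slide differences are excluded for the 6 erythroid genes, since the smallest fall of their mean within any slide was -2.087. Unequal washing of the perfused hearts could not be told from the same relation there (r = 0.098, permutation p = 0.646, adjusted p = 0.646, rho = 0.111, r without the 2 farthest 0.185, r with slide as a block 0.391, n = 20).

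Npy fell 18.3-fold to 24.9-fold with perfusion. Transcripts carried by blood cells may account for it: among the 10 non-perfused hearts Npy followed the erythroid genes (Pearson r = 0.839, permutation p = 0.00766, adjusted p = 0.0306 over 8 relations, Spearman rho = 0.782 with permutation p = 0.0222 and adjusted p = 0.0887, r without the 2 farthest arrays 0.668, r with slide as a block 0.806). With the platelet gene Clec1b r was 0.888 (permutation p = 0.0142, adjusted p = 0.0378, rho = 0.794, r without the 2 farthest 0.529), and in the 20 perfused hearts the relation to erythroid genes rested on 2 arrays (r = 0.639, permutation p = 0.0397, adjusted p = 0.0794, rho = 0.469, r without the 2 farthest 0.106). Th and Dbh, 2 enzyme genes of noradrenaline synthesis, had a mean change of -0.028 (95% interval -0.203 to 0.146). This argues against a general loss of sympathetic neuron transcripts. Whether their signal in the ventricle came from such neurons was not tested, so that loss is not excluded.

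Ribosomal protein and oxidative phosphorylation genes had a lower response to mannitol perfusion on sucrose (medians -0.131 and -0.157, and -0.146 over both lists), a camera call that was lost at an adjusted p of 0.318 with an estimated correlation for each list. Brightness-dependent differences between arrays could account for this, since the median over both lists was 0.003 with quantile normalization. The 4 noisy arrays and the lone array do not account for it, as the median stayed at -0.164 without them. Faults of other arrays were not tested. Slide differences are excluded at -0.137 with slide as a block. A smaller share of cardiomyocyte RNA cannot be told: macrophage minus endothelial markers changed by 0.226 (SE 0.134). The row on the slide stays open too, since 4 of 5 sucrose mannitol arrays lay in another row than the other 3 groups of this comparison.

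The list differences that follow were called by camera, but for none of the 3 interactions did fry or camera with an estimated correlation call any list. With mannitol, the median difference in response on sucrose was -0.257 for cardiomyocyte markers and 0.277 for macrophage markers (adjusted p = 0.318 with an estimated correlation for each). The sign of the cardiomyocyte median in the sucrose mannitol comparison turned with quantile normalization, as given in the results. With glucose it was -0.08 for heat shock genes (adjusted p = 0.168 with an estimated correlation, and 0.076 in the authors' values) and -0.056 for endothelial markers (adjusted p = 0.469 with an estimated correlation, and 0.074 in the authors' values). For glucose over mannitol it was -0.119 for matrix genes (adjusted p = 0.608 with an estimated correlation).

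Single arrays lay far from the other 4 of their group in 10 of 96 gene and group sets examined by Dixon's ratio, a test that chance alone trips in about 1 of 20 groups. Replicates have no order, and these are log2 levels. Txnip was at 3.463 in sucrose glucose replicate 3 (others 4.18 to 4.409). Npy was at -2.609 in chow mannitol replicate 3 (others -5.106 to -4.75) and at -3.266 in chow glucose replicate 4 (others -4.978 to -4.507). Cxcl1 was at 1.994 in sucrose mannitol replicate 2 (others 1.182 to 1.416) and at 4.254 in sucrose glucose replicate 1 (others 1.233 to 2.061). Bmal1, a core clock gene, was at -1.392 in chow non-perfused replicate 1 (others 0.274 to 0.644) and at -2.313 in sucrose non-perfused replicate 1 (others 0.321 to 0.45). Ciart was at -1.427 in sucrose non-perfused replicate 1 (others -6.406 to -5.332) and at -2.456 in sucrose glucose replicate 5 (others -1.201 to -0.872). In chow non-perfused replicate 1 Ciart was at -1.797 (others -6.687 to -4.934), which did not reach the limit of the ratio. Replicate 1 of both non-perfused groups thus had low Bmal1, and Ciart near the means of the perfused groups (-2.019 to -1.334). The standard deviation of negative controls was 13.906 in chow non-perfused replicate 2 (others 2.295 to 2.913).

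Each count of changed genes was set against 100 splits of the same arrays, the real one among them. Chance is excluded for the 4 perfusion comparisons, where only 1 split, the real one, gave as many: 1552 against at most 120 in any other, 1748 against 68, 1999 against 159 and 1597 against 371. For glucose against mannitol over both diets 3 splits gave at least the real 1 gene, with at most 230, so chance is excluded at that level. It cannot be excluded for Txnip alone in sucrose hearts (10 splits gave at least 1 gene, at most 2), for diet with mannitol (6 splits, at most 2) or for diet over all states (6 splits, at most 176). With 0 genes called, all 100 splits give as many, and the highest others were 1 for chow glucose against mannitol, 37 and 3 for diet without perfusion and with glucose, and 2, 55 and 1 for the interactions. The splits take no account of the slides. For the splits with the most genes over both diets (230) and over all states (176), slides were recorded for only part of the arrays. Among the chow arrays of the former and the non-perfused arrays of the latter, 3 arrays of slide 2 lay opposite 2 of slide 5. The sides of the other arrays were not recorded, so whether slide shaped these splits cannot be told. With slide as a block, Txnip over both diets (1.08, adjusted p = 0.00557) and Mt1 over all states (-0.73, adjusted p = 0.0379) were called.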

How the results depend on the processing

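The alternatives were planned before the data were examined, except leaving out the 4 noisy arrays, chosen after. For every change given here the cause was not tested.

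Counts of the 4 perfusion comparisons (1552, 1748, 1999 and 1597) were weaker with normexp (823, 924, 931 and 814) and with the authors' values (361, 421, 413 and 447), and leaving out 1 array gave 1291 to 1427, 1481 to 1611, 1561 to 1849 and 1274 to 1535. The share of changed genes that rose was 57.0%, 57.0%, 50.8% and 63.6%, against 67.0%, 71.2%, 58.9% and 67.3% with normexp and 86.1%, 72.0%, 88.9% and 91.7% in the authors' values. Of the genes called with mannitol in chow, 1467 were also called with quantile normalization. The sucrose mannitol count was 1252 without the 4 noisy arrays, 1022 without these and the lone array and 1070 with only the compared groups, which gave 1046 for sucrose glucose.

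For glucose against mannitol in sucrose hearts the 1 gene became 2 with quantile normalization, slide block, array weights or without the lone array (the last 3 adding Zfp354c), and 0 with the authors' values, replicate block or only the compared groups (0 to 2 with 1 array left out). Over both diets it was 2 without the 4 noisy arrays and the lone array, and always 1 with 1 array left out.

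For diet with mannitol the 1 gene became 0 with normexp, the authors' values, no filter, replicate block, only the compared groups and both removals of noisy arrays (0 to 1 with 1 array left out). For diet with glucose array weights gave 1.

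For diet over all states the 1 gene, Mt1, became 0 with quantile normalization, the authors' values, no filter, replicate block and both removals of noisy arrays. It became 8 with normexp, 6 with the mean of probes, slide block or random slide block, 5 with array weights, 4 with a filter on all arrays or trend and robust options, and 3 without the lone array (0 to 4 with 1 array left out). Mt1 lay between -0.842 and -0.653 over all of these.

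Among the named genes, signs turned in 4 values that were called in either fit or lay further from 0 than their SE in the main fit. Other changes of sign were not counted. The lists whose medians turned are given in the report. Myl4 with sucrose mannitol perfusion was 0.018 with quantile normalization and 0.096 in the authors' values. Hk2 was -0.058 for diet without perfusion and 0.09 for the glucose interaction in the authors' values.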

Other observations

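The patterns here were picked after the results were seen, and what each test should show was written down before it was run.

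Txnip was higher with glucose than with mannitol in both diets. It passed the threshold over both diets and in sucrose hearts. Of 100 splits, which count genes of any name, 3 gave as many genes over both diets and 10 in sucrose hearts. The splits thus exclude chance at that level over both diets but not in sucrose hearts. In sucrose hearts the call ended without any one of 5 arrays and in the authors' values (adjusted p = 0.155). In chow hearts the adjusted p was 1, and glucose cannot be separated from the row of the slide. No other gene passed in the chosen settings, and Zfp354c, a zinc finger gene, was called as lower in sucrose hearts in some others. The level of Txnip with glucose was 4.08 in chow and 4.09 in sucrose hearts, and with mannitol 3.25 and 2.82. Over all states, Mt1 was lower on sucrose, a call that ended in 21 of 30 fits without 1 array and for which the splits do not exclude chance. The fatty acid oxidation list was lower on balance (fry adjusted p = 0.0082, but camera adjusted p = 0.0574 with an estimated correlation), with Angptl4 at -0.77 and Pdk4 at -0.38. The rise of Angptl4 and Pdk4 with perfusion came with both buffers.

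Clock genes rose with perfusion, and hearts taken at different times of day may account for part of it. Over 30 arrays, group means removed, Bmal1 ran against the mean of Ciart, Per2 and Dbp (Pearson r = -0.818, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 8e-05 over 8 relations, Spearman rho = -0.834, r without the 2 farthest arrays -0.829). With Bmal1 as a covariate the rise of the 3 genes was 1.071 (95% interval 0.534 to 1.607), against 2.052 without it, so perfusion itself could also play a part. Bmal1 itself fell by 1.727 with perfusion (95% interval -2.821 to -0.634), so it is not a measure of phase free of perfusion, and the 2 explanations stay open. Recording the hour of each heart's removal would separate these.

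Myl7 and Sln, genes more strongly expressed in atria, varied widely between hearts of one group. Atrial tissue in some samples might do this, but their relation could not tell (Pearson r = 0.357, permutation p = 0.107, adjusted p = 0.172, Spearman rho = 0.374, r without the 2 farthest arrays 0.531, n = 30).

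Lower glucocorticoid signalling in sucrose-fed rats might lower Mt1 and the glucocorticoid-responsive genes together, but their levels were not clearly related (Pearson r = 0.22, permutation p = 0.287, adjusted p = 0.383, Spearman rho = 0.206, r without the 2 farthest arrays 0.116, n = 30). Serum corticosterone of the same rats would test it.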
